A study of Capsicum annuum with 5 samples.

How the data were processed

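Total RNA from roots, stems, mature leaves, open flowers and fruits of pepper was extracted with Trizol, and libraries were made with an Illumina small RNA kit and read on a HiSeq2000, per the labels' protocols. Roots, stems and leaves came from plants grown at 22 °C with 16 h of light. No temperature or light was recorded for flowers and fruits, so growing conditions may differ between these and the other tissues. The labels disagree on the fruit: the sample label names a mature green stage and the series text a fruit turning red 30 days after pollination, so the stage is left open and the group is called fruit. The extraction text speaks of root samples for all tissues, and the tissue of each library was taken from its own sample label.

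The deposited data were a genome annotation in GFF version 3 written by a plant setting of the MIREAP miRNA finder, per the file headers. Each mature sequence carried a whole-number tag count for each of the 5 libraries in its deposited attribute text. No scaling is recorded there. The genome build, aligner, read trimming, rule for tags with several matches and library totals are not given in the sources used here. In the deposited counts, 36 sequences stood on more than 1 hairpin, and for 18 of these the counts were identical at every hairpin, so sums over hairpins count such tags repeatedly. For the other 18 the counts differed between hairpins in at least 1 library.

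The annotation held 490 lines, 176 for precursors and 314 for mature sequences. As 10 precursors were repeated with identical content, each was kept once. On 138 mature lines the listed position did not match the length or place of the sequence, and on 68 the end lay before the start, so mature positions were computed from the precursor's position and the sequence within it. In 5 cases the mature name did not match its parent hairpin (1 of miR1446 and 4 among candidates from miRC26 on), and the parent was used. Arms were taken as the annotation types them. A family is the number in the name, and candidates are the hairpins named miRC. In 16 hairpins every library was at 0. Totals of 1 to 4 tags per hairpin and library were nearly missing, so a value of 0 is called listed at 0 and no fold size is given against it. The 4-fold criterion took such values as 0 and, as an alternative, as 4.

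The strand share was tested with a two-sided exact binomial test, and shares have 95% Clopper-Pearson intervals. Tests set for the share of arms and for first bases of 24 nt sequences are not reported, because most hairpins list both arms and because only 1 sequence had that length. Neighbours of a family within 10 kb, measured between ends on either strand, were compared with 10000 shuffles of the family names over fixed positions (one-sided). Precursor lengths of candidates and numbered families were compared with a permutation test of the means (100000 resamples, two-sided). Family counts were summed over all listed mature sequences, divided by the library's listed total and given per 1000000 listed tags (normalised tags). Differences are on the scale log2(value + 1), which understates changes of families with low counts. Folds are ratios of normalised values, with 95% intervals from the exact binomial split of the counts, each sequence taken once. Poisson intervals for the 4-fold criterion were likewise computed from counts with each sequence taken once. Families with fewer than 10 tags over the 5 libraries were left out of comparisons between tissues. Besides division by listed totals, 3 other scalings were run: median-of-ratios size factors (31 families), totals without miR166, and each sequence counted once. Guide arms of 23 families came from a table of textbook knowledge written after the data were seen.

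Families to name were fixed before the data were examined: the 10 families with most hairpins, lists of development, nutrient and copper, small RNA pathway, NLR and Solanaceae families, groups of 3 or more hairpins within 10 kb, the longest and shortest precursor, the 10 most abundant families and the 3 families per tissue with the largest lead over the next tissue. Others, such as miR4414, miR403, miR1446 and the arms of miR397a, miR398 and miR482, were chosen after their values were seen. Alternatives covered merging of overlapping hairpins, windows of 5 and 50 kb, weighting by sequence or family, count minimums and a pseudocount of 10. Tests against chromosome lengths or gene numbers and the genomic context of hairpins were left out, since no genome or annotation of the same build was used here. The 4-fold criterion was tested on simulated Poisson counts of 57 families, with division by totals only. With 10 families raised 8-fold in a tissue, 100% were recovered over 50 simulations, and 0% of those raised 2-fold were called. Only families of low share with enough expected tags in every library were raised, so recovery of families with few tags was not tested. The simulated counts had no minimum before listing. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.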

Results

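Small RNA from 5 tissues of the pepper inbred line Zunla 1 (Capsicum annuum) was sequenced, with 1 library each for root, stem, mature leaf, open flower and fruit. The deposited annotation listed 134 distinct hairpins of numbered miRNA families, 31 hairpins of candidate miRNAs and 314 mature sequences cut from them, each mature sequence with its tag count in every library. The counts summed over the listed mature sequences were 552707 in root, 1062218 in stem, 1302815 in leaf, 2395834 in flower and 1143163 in fruit. With each sequence taken once per family they were 231560, 318815, 542531, 678695 and 311417 in the same order. These sums cover annotated miRNAs only and are not the depth of the libraries. With 1 library per tissue no difference between tissues has a replicate check, no p-value is given for any of them, and all count intervals cover counting error only.

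The hairpins fell into 64 families, of which 35 carried established miRNA numbers (134 hairpins) and 29 carried candidate names beginning with miRC (31 hairpins). The largest families were miR169 with 12 hairpins, miR395 with 11, miR171 with 10, and miR156, miR166, miR172 and miR399 with 9 each. They were followed by miR162 with 6, miR398 with 5 and miR164 with 4, a size that miR167, miR396 and miR482 shared. The 10 families named first held 84 hairpins, 50.9% of the total, while 37 families had a single hairpin.

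Among families that in plants target transcription factors, F-box genes or the TAS3 transcript, 14 of the 17 looked for were listed, with 74 hairpins. Besides those already named, they were miR159 and miR319 with 3 hairpins each, miR160, miR390 and miR394 with 2 each, and miR393 with 1, whereas miR157, miR165 and miR170 had 0. Here and below, 0 means that no hairpin carried that number in its name. It does not show that the sequences are absent, as related sequences may be listed under another number. Of the nutrient and copper families, miR397 had 2 hairpins and miR408 had 1, and miR827 and miR857 had 0. The small RNA pathway was covered by miR162, which targets DCL1, by miR168 with 2 hairpins, which targets AGO1, and by miR403 with 1, which targets AGO2. Of the 13 families looked for as regulators of NLR disease resistance genes, miR482, miR5300 (1 hairpin) and miR1507 (1 hairpin) were listed, and miR2118, miR2109, miR6019, miR6020 and miR6022 to miR6027 had 0. Of the Solanaceae families, miR4376, miR5300 and miR5301 had 1 hairpin each and miR5303 had 3, and miR1919, miR5302 and miR5304 had 0.

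Chromosome 3 carried the most hairpins, 22, among them 5 of miR162 and 3 of miR167, and chromosome 4 the fewest, 4. Chromosome 11 carried 16, chromosomes 1 and 7 carried 14 each, and the remaining numbered chromosomes between 9 and 13. A further 20 hairpins lay on the sequence named Chr00. Chromosome lengths of the build were not used here, so these are counts and not densities. Of all hairpins 85 lay on the plus strand, 51.5% (95% Clopper-Pearson interval 43.6 to 59.4, two-sided exact binomial p = 0.756).

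Hairpins of a family lay side by side more often than family names shuffled over the same positions. In total 22 hairpins had a member of their own family within 10 kb, against a mean of 0.736 and a maximum of 8 in 10000 shuffles (one-sided permutation p = 0.0001, the smallest the shuffles can give). They formed 11 pairs in 9 families, and no family had 3 or more hairpins within 10 kb of each other. The closest separate pair was miR477a and miR477b on chromosome 8 (124212029 to 124212273), 62 bp apart. miR395 and miR169 each had 2 pairs, with miR395a and miR395b on chromosome 11 (183111286 to 183112012) and miR169h and miR169i on chromosome 7 (19828134 to 19828652) among them. In 2 pairs, miR156h with miR156i on chromosome 9 (1598999 to 1599089) and miR397a with miR397b on chromosome 7 (217000382 to 217000475), both hairpins had the same coordinates on opposite strands. The remaining pairs belonged to miR159, miR396, miR398 and miR1446. The genome build behind these positions is not given in the sources used here.

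**Figure D1:**
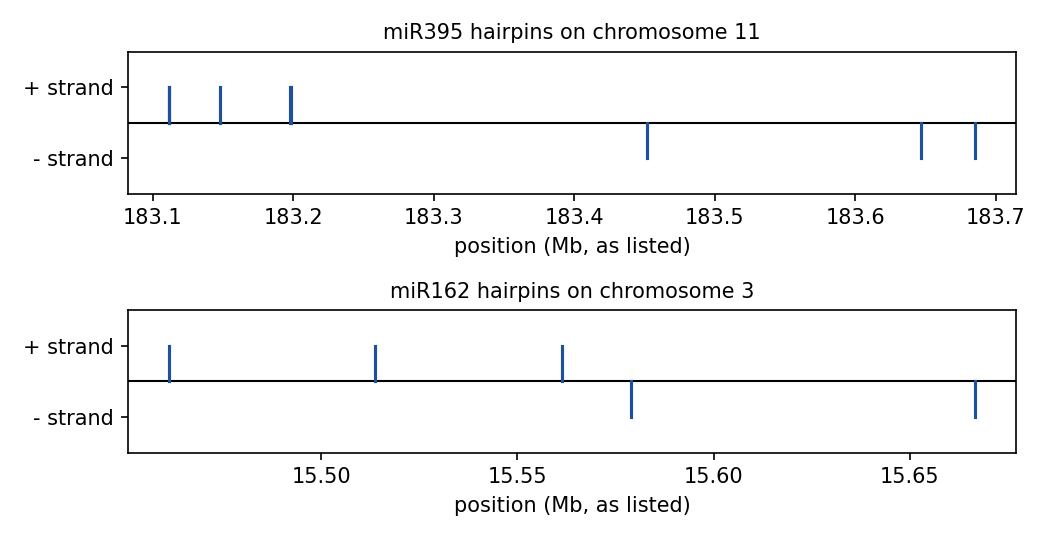
Positions of the miR395 hairpins on chromosome 11 (upper) and the miR162 hairpins on chromosome 3 (lower), in Mb as listed, with a bar for each hairpin above the line on the plus strand and below it on the minus strand. The 8 miR395 hairpins span 574 kb and the 5 miR162 hairpins span 206 kb, and very close miR395 bars overlap.

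On a wider scale, 8 of the 11 miR395 hairpins, whose family targets sulfate assimilation genes, lay between 183111286 and 183685432 on chromosome 11. Their 8 listed mature sequences took only 2 distinct forms. On chromosome 3, 5 of the 6 miR162 hairpins lay between 15461100 and 15666813. These groups were found by linking hairpins of a family less than 500 kb apart, a distance chosen after the data were seen, which also gave groups of 3 for miR169 on chromosome 7 and for miR398 on chromosome 11.

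Precursors had a mean length of 118 nt (SD 46.7 over all hairpins, median 101). The shortest was miR171b with 58 nt, on chromosome 1 (28071863 to 28071920), and the longest miR2873a with 321 nt, on chromosome 12 (229015302 to 229015622). The 31 candidate precursors averaged 136 nt (SD 53.8) and the 134 precursors of numbered families 114 nt (SD 44.1), a difference of 22.2 nt (two-sided permutation test, p = 0.0263). With 1 value per family the difference was 20.02 nt and no longer passed the permutation test (p = 0.110).

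Of the 314 mature sequences 240 were 21 nt long, 76.4% (71.3 to 81.0), and 42 were 22 nt long, 13.4% (9.81 to 17.6, Clopper-Pearson intervals). U was the most frequent first base, in 152 of 314 or 48.4% (42.8 to 54.1), followed by G with 22.3%. The 314 include sequences repeated at several hairpins, which the intervals treat as independent. Of the 245 distinct sequences, 73.1% were 21 nt long and 43.7% began with U. Only 1 sequence, the 3′ arm of miRC11, was 24 nt long. The 5′ arm supplied 155 of the 314 mature sequences (49.4%), and 134 hairpins listed a sequence from each arm.

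miR166, a regulator of class III HD-ZIP transcription factors, was the most abundant family in every library, with 56.3% of the listed tags in root, 77.9% in stem, 60.2% in leaf, 59.1% in flower and 77.9% in fruit. These sums count a tag at each hairpin that lists it, and with each sequence taken once the shares were 36.2%, 44.7%, 32.2%, 40.7% and 62.3% in the same order. miR156, which targets SPL transcription factors, was highest in flower, with 28.3% of the tags against 1.16% in fruit, a 24.3-fold difference (95% counting interval 23.7 to 24.9, and 13.1 to 44.3 over the 4 ways of scaling). miR167, which targets auxin response factors, was highest in fruit with 14.1% and lowest in stem with 0.196%, a 72.0-fold difference (66.1 to 78.7, and 72.0 to 125 over the scalings). miR172, which targets AP2-like factors, was highest in root with 30883 normalised tags (tags per 1000000 listed tags of the library) against 2972 in flower, a 10.4-fold difference (9.94 to 10.9, and 2.95 to 10.4 over the scalings). Its lead over leaf was 1.98-fold (1.80 to 2.73 over the scalings). miR168 had its highest normalised value in root (115560), but in flower under median-of-ratios scaling. Together the development families took 77.8% of the listed tags in leaf and 94.9% in flower, or 47.0% and 82.7% with each sequence taken once. These were the lowest and highest tissues except with totals without miR166, where root was lowest and fruit highest. The small RNA pathway families took 12.3% in root and 3.90% in fruit, or 28.3% and 13.8% with each sequence taken once. Root was highest except under median-of-ratios scaling, where flower was, and the lowest tissue changed between fruit, stem and flower with the scaling.

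**Figure D2:**
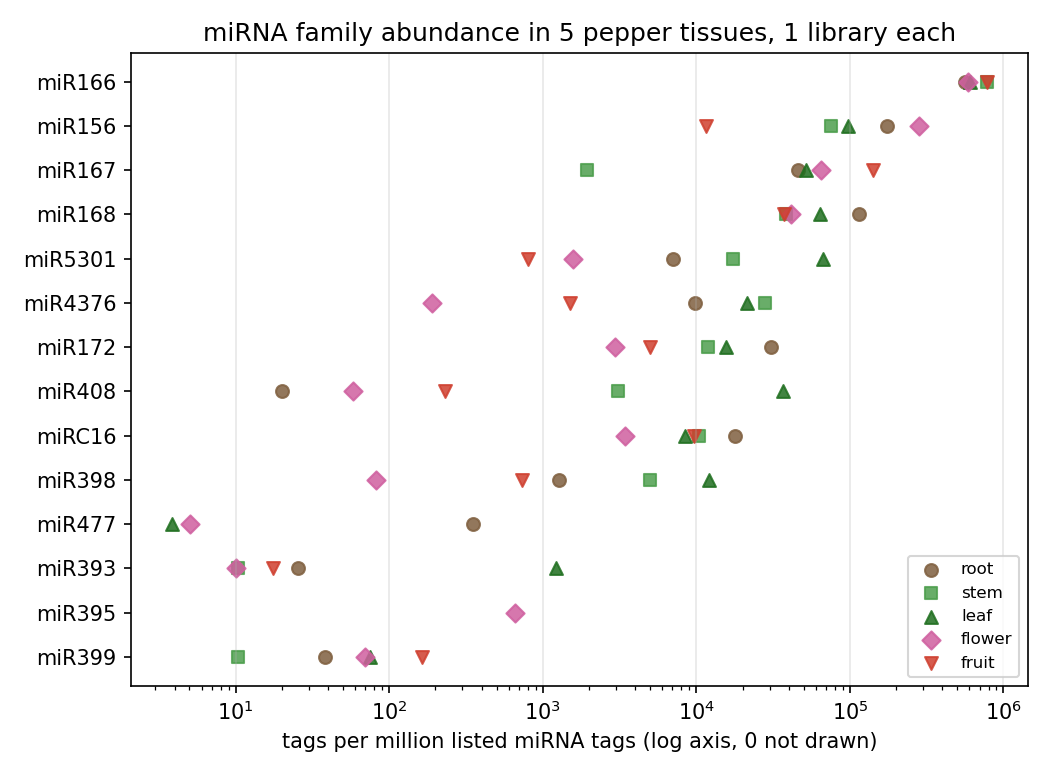
Tags per 1000000 listed miRNA tags (log axis) in root, stem, leaf, flower and fruit, 1 library each, for the 10 most abundant families and the numbered families that stood farthest above the next tissue. miR408 lies at 36912 in leaf and 19.9 in root, miR167 at 1955 in stem, and miR395 has a point for flower only, being listed at 0 elsewhere.

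The choice of scaling mattered for the comparison of tissues. Over the 31 families with tags in all 5 libraries, the median family's normalised value lay below the 5-library reference in flower (-1.36 log2 units) and fruit (-0.50) and above it in leaf (0.63), root (0.46) and stem (0.30). Median-of-ratios scaling therefore divided each fold over flower by 3.97 for leaf, 3.53 for root, 3.15 for stem and 1.82 for fruit. Each direction given here held under all 4 scalings unless a flip is named.

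Leaf had the highest values of the copper families miR408, miR398 and miR397 and of miR5301. miR408, whose targets are copper proteins, had 48090 tags in leaf and 3277 in stem, a 12.0-fold difference in normalised tags (11.5 to 12.4, and 6.64 to 12.0 over the scalings), and 11 in root. miR398, a regulator of copper/zinc superoxide dismutase, reached 12053 normalised tags in leaf and 82.2 in flower, a 147-fold difference (127 to 170, and 36.9 to 150.5 over the scalings), but its lead over stem was 2.41-fold and 1.34-fold with totals without miR166. miR397, which targets laccases, had 6793 and 350, a 19.4-fold difference (18.1 to 20.9, and 4.89 to 19.9 over the scalings), and its lead over root was 1.71-fold (1.51 to 1.87 over the scalings). That lead includes passenger tags, 2238 in leaf and listed at 0 in root. Guide arms of miR397 had 6612 tags in leaf and 2202 in root, a smaller lead. The nutrient and copper list took 5.58% of the listed tags in leaf and at most 1.03% elsewhere, or 13.4% and at most 3.43% with each sequence taken once. Most of these leaf tags came from passenger arms, with 48088 for miR408 and 15338 for miR398 against 2 and 365 from guide arms. In miR397 the guide arms had more. The size of the leaf lead of the list thus rested largely on passenger arms, though the guide arms of miR397 alone were also highest in leaf. miR5301 was 3.82-fold higher in leaf than in stem (3.76 to 3.88, and 2.12 to 3.82 over the scalings) and 82.4-fold higher than in fruit (77.2 to 88.0, and 37.8 to 82.4 over the scalings). The Solanaceae list took 8.81% of the listed tags in leaf and 4.67% in stem, a 1.89-fold lead that fell to 1.05-fold with totals without miR166. Of its 4 listed families only miR5301 was highest in leaf under all scalings. miR4376 was highest in stem with 28175 normalised tags, next to 21355 in leaf and 190 in flower, miR5300 was highest in root, and the highest tissue of miR5303 changed with the scaling. miR393, which targets auxin receptor F-box genes, had 1586 tags in leaf and between 11 and 24 in each other library, and was 48.1-fold higher in leaf than in root (28.6 to 88.1). All 1586 leaf tags were from its passenger arm. The guide arm was at 0 in root, stem and leaf, with 1 tag in flower and 4 in fruit.

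In miR408, miR393, miR398, miR160 and miR399 most tags came, in every library, from the passenger arm and not from the arm known to guide silencing. With each sequence taken once, the passenger arm held between 97.1% and 100% of the miR408 tags, between 80.0% and 100% for miR393 and between 67.5% and 97.7% for miR398. It held between 90.8% and 99.0% for miR160 and between 62.3% and 100% for miR399. For miR171 it held between 61.4% and 91.9%, but summed over hairpins it held 42.2% in leaf and 24.3% in fruit. In leaf 48088 of the miR408 tags came from its 5′ arm and 2 from the 3′ guide arm. The miR398 guide arms had 406 tags in stem and 365 in leaf and were highest in stem after normalisation, while the passenger arms had 15338 in leaf and 4902 in stem. Leaf differed from the other libraries in miR397 and miR482. The 3′ arm of miR397a had 2238 tags in leaf and was listed at 0 in the other tissues. For miR482 the 5′ arms made up 88.6% of the leaf tags and between 3.47% and 19.2% in the other libraries. The names and typed arms of miR482c disagreed, and with its arms taken from the names the leaf share was 87.4%.

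Root led for families tied to disease resistance genes. miR5300 had 4518 normalised tags in root, 1090 in stem and 290 in leaf, and its lead over stem fell from 4.14-fold to 2.09-fold with totals without miR166. miR482 had 2935 in root, 1772 in leaf and 370.2 in flower, and its lead over leaf was 1.66-fold (1.51 to 1.86 over the scalings). With arms as typed, 2045 of its leaf tags were from passenger arms, against 82 in root. The guide arms of miR482 alone had 1540 tags in root, 878 in stem and 264 in leaf, so their root lead over leaf was larger. The NLR list took 0.748% of the listed tags in root and at most 0.214% elsewhere, or 1.79% and at most 0.712% with each sequence taken once. miR1507, with 65 tags in all, was highest in root after normalisation but in stem under 2 of the other scalings. miR477 had 194 tags in root, 12 in flower and 5 in leaf and was listed at 0 in stem and fruit. miR171, which targets GRAS factors, had 3244 normalised tags in root and 851 in flower, though the gap to flower narrowed to 1.08-fold under median-of-ratios scaling. With each sequence taken once, 1471 of its root tags were from passenger arms and 130 from guide arms, and the guide arms alone were highest in flower under median-of-ratios scaling. miR162 was highest in root as well, with 7170 normalised tags against 2920 in stem, a 2.46-fold lead that fell to 1.24-fold with totals without miR166, and miR319, with 109 tags in all, was led by root with 73, of which 61 were from passenger arms. The candidates miRC2 (160 tags in root over 2 hairpins, at most 28 elsewhere) and miRC26 (16 tags in root, listed at 0 elsewhere) stood beside them.

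Stem was marked by miR164, which targets NAC transcription factors, with 10261 normalised tags against 2106 in fruit, a 4.87-fold difference (4.66 to 5.10) that fell to 2.81-fold under median-of-ratios scaling. miR4414 had 1728 tags in stem and 222 in root. The candidates miRC11, miRC21 and miRC10 had 427, 42 and 18 tags in stem and were listed at 0 in the other tissues. In flower miR395 had 1585 tags, summed over 11 hairpins that mostly share their tags, and was listed at 0 elsewhere. That sum was 9.97 times the count with each sequence taken once. The candidates miRC18 and miRC5 had 204 and 154 tags in flower and were listed at 0 elsewhere. miR160 and miR394 were highest in flower too, with 510.5 and 95.2 normalised tags, though for miR160 passenger arms had 1179 of the flower tags and guide arms 44. In fruit miR399, a regulator of phosphate balance, had 188 tags, 1.13 log2 units above leaf, a lead that was 0.37 over the next tissue under median-of-ratios scaling. With each sequence taken once, 130 of its fruit tags were from passenger arms and 36 from guide arms, and the guide arms alone were highest in flower under median-of-ratios scaling. The candidate miRC17 had 36 tags in fruit over 2 hairpins and was listed at 0 elsewhere. Leaf gave the candidate miRC22 with 10 tags.

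Of the 57 families with at least 10 tags, 21 had their highest normalised value in root, 14 in leaf, 11 in stem, 7 in flower and 4 in fruit. Under median-of-ratios scaling these numbers were 18, 8, 7, 14 and 10 in the same order, and with totals without miR166 stem had 19 and root 14. The tissue was the same under all 4 scalings for 38 of them, including miR156, miR167, miR172, miR398 and miR408. The exceptions among the abundant families were miR166, miR168, the candidate miRC16, miR396, miR159, miR390 and miR169. In all, 17 families were at least 4-fold higher in a single tissue than in every other with separate Poisson intervals, 6 in root, 5 in stem, 3 in flower, 2 in leaf and 1 in fruit. For 8 of them every other tissue was listed at 0, so that no fold size can be given, and with values of 0 replaced by 4 the number was 15. Of the 17, 12 passed under each scaling and with values of 0 replaced by 4, an alternative chosen after the data were seen, among them miR393, miR395, miR408, miR477 and miR4414.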

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

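The alternative with 0 replaced by 4, the repeated precursor lines and all settings for the passenger arms were chosen after the data were seen. The counts of hairpins and families, the strand share, the share of U and the number of families at least 4-fold higher in a single tissue kept their direction or stayed within 1.5 times under every alternative run for them. Clustered hairpins numbered 35 within 50 kb and 14 on the same strand only, each beyond the shuffled values (permutation p = 0.0001). Precursor length was 101 nt as a median and 128 nt with 1 value per family, which also took the candidate difference to 20.02 nt (permutation p = 0.110). The 21 nt share was 69.7% with 1 vote per family. Median-of-ratios scaling moved the number of families highest in stem to 7, in leaf to 8, in flower to 14 and in fruit to 10. Totals without miR166 gave 19 for stem and 7 for fruit, each sequence counted once gave 7 for fruit, and at least 100 tags left 9 for leaf. The median leaf shift of passenger arms was 2.34 with at least 100 passenger tags, a minimum that counts leaf tags and so favours the shift. The cause of these changes was not tested. For single named families and counts per tissue, 43 of the alternatives set before the data were examined moved a value beyond its counting interval or by over 1.5 times and 74 did not, and of those added later 9 did and 19 did not. No named family at least 4-fold higher in a tissue changed direction. Alternatives that need gene numbers or gene positions of the same build were not run. Low counts limited small candidates: with 0 replaced by 4, the log2 lead over the next tissue was 1.98 for miRC17 and 1.12 for miRC10, below 4-fold, and 0.07 for miRC22.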

Other observations

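The tests of families listed at 0 were chosen after their result was seen, and the passenger arm pattern was found in these data before its tests were written. The miR156 and miR172 families differed between tissues in which sequence they contributed. The form TTGACAGAAGATAGAGAGCAC made up 94.7% of miR156 5′ arm tags in flower and 89.2% in leaf, but 44.8% in root, where TGACAGAAGAGAGTGAGCAC reached 39.2% with 14193 tags. In fruit the leading form was TTGACAGAAGAGAGTGAGCAT with 53.5%. Of the miR172 3′ arm tags in root, 48.0% carried TGAATCTTGATGATGCTGCAT (3287 tags), a form at 0.434% in leaf. For miR166 the form TCGGACCAGGCTTCATTCCTC ranged from 20.1% of 3′ arm tags in stem to 56.5% in root. These shares take each sequence once and are within libraries, so dividing by library totals or size factors does not change them. Summed over hairpins they would differ, because the forms stand on different numbers of hairpins, for miR166 7 and 2.

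The candidate miRC16 on chromosome 3 had 9883, 11061, 11013, 8180 and 11026 tags in root, stem, leaf, flower and fruit, a coefficient of variation of 12.2% in unscaled counts, 52.2% in normalised tags and 34.5% under median-of-ratios scaling. miR403 had 351 tags in root and 372 in stem but 13 in leaf and 7 in flower, all of these from its passenger arm. miR1446 had 508 tags in leaf and was listed at 0 in flower and fruit. Among families with at least 10 tags, 25 of the 34 numbered ones but 6 of the 23 candidates had tags in all 5 libraries. Most candidates had few tags in all, and families with few tags were more often listed at 0. Abundance and candidate status therefore cannot be told apart in this contrast. Of the hairpins with tags on both arms and a readable structure, 100 of 107 had overhangs of 2 nt at both duplex ends, 93.5% (Clopper-Pearson 87.0 to 97.3), with 17 of 18 among candidates. Of those with tags on 1 arm or none, 16 of 19 had them as well, 84.2% (60.4 to 96.6). Listed arms thus mostly had such overhangs with or without tags, and the share is no evidence for the candidates. In the 23 families with a known guide arm, U began 72.0% of guide (63.0 to 79.9) and 11.7% of passenger sequences (5.99 to 19.97). These intervals treat sequences repeated at several hairpins as independent. With each distinct sequence taken once the shares were 69.1% and 12.0%. Arms are as typed here, and the 2 miR395 lines typed as passenger (miR395b and miR395k) repeat a guide sequence of that family.

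The passenger arms of conserved hairpins took a larger share in leaf: over 52 hairpins with at least 20 tags in each library, the log2 ratio of passenger to guide in leaf lay a median of 1.86 above the mean of the other 4 tissues (95% bootstrap interval over families 1.38 to 2.33), with 0.5 added to each arm. Without the 4 hairpins that had no passenger tag in any library the median was 2.04 (1.39 to 2.36), with 44 of 48 hairpins and 16 of 16 family medians higher. With at least 20 passenger tags in the other 4 libraries it was 1.93 (1.34 to 2.36), with 28 of 31 hairpins and 11 of 12 family medians higher. Hairpins of a family can share sequences and are not separate observations. Tests argue against 3 technical explanations as the whole cause: the median was 1.86 (0.52 to 2.71) over 24 hairpins whose arms differ by at most 1 G or C, 1.45 (0.91 to 2.11) over 45 hairpins whose passenger sequence is listed once, and 1.92 (0.86 to 3.03) over 13 families without the most abundant families. With that minimum in the other libraries they were 1.66 (0.04 to 2.32), 1.49 (0.83 to 2.33) and 1.69 (0.45 to 2.56). There, 4 of 6, 11 of 12 and 9 of 10 family medians were higher, in the same order. A difference in library preparation, RNA quality or degradation in this single leaf library and a difference in arm use in leaf tissue may both be consistent with the shift and were not tested.

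Several families were listed at 0 in some tissues, and only 1 of 40 hairpin totals between 1 and 8 tags was below 5, 2.5%, which is consistent with a minimum tag count per hairpin and library before listing. Lower depth of the other libraries, judged from listed tags, does not account for all 10 families with tags in a single tissue. At equal abundance at most 0.749 of them would be expected at 4 or fewer tags in every other library under any of 4 scalings. Lower depth stays open for miRC22 and miRC24, with 10 tags each. With each sequence taken once, the lowest count expected elsewhere had a median of 26.3 by listed totals and 20.8 by size factors, or 19.5 with the lower of both per family, where it was 36.7 for miR395 and 222 for miRC11. The median of 19.5 was the measure set first, which could not decide, and it was replaced after the values were seen. No biological explanation was tested.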
